A study of Homo sapiens with 2 samples.

How the data were processed

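Total RNA from 2 cultures was measured on 1 Affymetrix array each. One culture was the parental human breast cancer line MDA-MB-231 and the other its variant MDA-MB-231(SA). Per the labels' protocols, both were grown in flasks in a medium with 10% serum and 1000 mg/L glucose, RNA was taken with a column kit, and biotin-labelled cRNA was made from 3 µg of it. There was 1 array per group and no replicate, so no statistical test was possible and no p-value is given. The array names in the labels carry the same suffix, so nothing in them separates the arrays into batches.

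The values deposited by the authors are log2 expression levels. RMA, which corrects background, makes the arrays' probe distributions equal and summarises the probes of each feature, is named in the submitters' processing notes. Its software version, the array model and the probe set definition are not given in the sources used here. The log base is not given either; 2 was taken because RMA writes log2 values and because the values ran from 2.50 to 14.5. The table held 18394 features with no missing value, and each row was 1 Ensembl gene ID, so the probes had been regrouped by gene. No ID occurred more than once, and the table used here held 0 control rows. RMA shrinks differences of dim features towards 0, because background signal remains in their values. A fold given below is 2 to the power of a difference of such values, so this effect alone would make it understate changes of features that are dim on one array. Choosing the largest differences between 2 arrays without replicates can act the other way.

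The rows carry no gene symbols. Of the 18394 IDs, 0 matched the gene table used here, in which 0 rows carried an Ensembl ID, so genes are given by ID, and only the 2 with the largest difference in each direction are printed. Before the data were examined, 26 gene lists, 6 cell type marker lists, a comparison by chromosome, a comparison of probe sets of 1 gene and a check of RNA quality on control probe sets had been fixed. The lists and the chromosomes needed symbols, the probe set comparison needed several rows per gene, and the quality check needed control rows. They are not analysed here, and neither are the genes named in advance (those of serine synthesis and of bone breakdown). The rule for named genes had asked for the 15 largest differences in each direction and for members of the lists.

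From the deposited log2 values, the difference SA variant minus parental was taken for each gene. A level floor was set at the median of all values on both arrays, 5.62, and a gene was compared when it reached the floor on at least 1 array. A gene was counted as higher or lower when its difference was at least 2-fold (1 on the log2 scale). This is a rule of size, and no count made with it is a count of significant genes. For the closing section, 4 lists of Ensembl IDs on the cell cycle were added after the data had been seen. They were taken from a published set of human marker pairs supplied with an R package, which had been trained on single cells of a human embryonic stem cell line sorted by cycle phase. The first list holds all 1314 genes of that set, all with a cell cycle annotation. The others hold the genes that stand more often as the higher partner in the pairs of 1 phase and more often as the lower partner in the pairs of the other phases, which gave 213 genes for G1, 219 for S and 127 for G2/M. The median difference of a list was placed among 10000 random lists of the same size, matched on mean level in 20 bins, and was taken to stand apart at or below percentile 2.5 or at or above percentile 97.5. Genes of one list are not independent of each other, so these percentiles describe the 2 arrays and are no p-values.

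The alternatives fixed before the data were examined were floors at the 25th and 75th percentile, no floor, the floor required on both arrays, the difference centred on its median, a lowess trend on level subtracted (span 0.4) and size rules of 1.5-fold and 3-fold. Quantile normalization of the 2 columns to each other was added after the data had been seen. So were 3 alternatives for the cell cycle lists only: the mean of the members, matching in 5 bins and random lists without matching. Alternatives that pool or leave out probe sets of a gene were not run, since each gene had 1 row. The rules were tested on simulated data made from the parental array's 18394 features. Of the 150 features changed by 1.5, 2 or 3 on the log2 scale, 99.3% passed the 2-fold rule in the simulated direction, and 2 unchanged features passed it. The changed features were drawn only from features well above the floor on the parental array. The simulated noise was also made smaller than the spread between the real arrays. The 99.3% therefore does not hold for dim features or for real noise. The 2 unchanged features say nothing about how many real calls are noise. Of 40 simulated lists of 120 genes shifted by 0.3, 40 stood apart, and of 40 unshifted lists 2 did. That shift was larger than the one found for any cell cycle list, such as -0.122 relative to random lists for the S list. The simulated lists were also drawn at random, so their members were not regulated together. These numbers therefore do not tell how often real lists of the reported sizes stand apart, rightly or wrongly. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.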

Results

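Gene expression was compared between the parental MDA-MB-231 line, a human breast cancer line without oestrogen receptor, and MDA-MB-231(SA), a variant of it known for forming bone metastases in mice. Each was profiled on 1 array, and the table covered 18394 genes, each identified by its Ensembl ID. The values on the parental array had a median of 5.60 and quartiles of 4.12 and 7.61 on the log2 scale. On the SA array the median was 5.64 and the quartiles were 4.10 and 7.66. At or above the level floor of 5.62 lay 9146 genes on the parental array and 9248 on the SA array. On at least 1 of them lay 9725 genes, which were compared, while 8669 genes stayed below the floor on both. With 1 array per line, no difference below has a replicate check, and the number of arrays limits the precision of every value.

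The comparison asked which genes differ in expression between the SA variant and the parental line. Of the 9725 genes compared, 559 (5.75%) were at least 2-fold higher in the SA variant and 406 (4.17%) were at least 2-fold lower. The other 8760 genes (90.1%) differed by less than 2-fold. The median difference of the genes compared, SA variant minus parental, was 0.045 on the log2 scale, with quartiles of -0.29 and 0.39. The central 95% of their differences ran from -1.20 to 1.42. Over all 18394 genes, without a floor, the median difference was -0.0045. The 2 profiles had a Pearson r of 0.970 and a Spearman rho of 0.969 across all 18394 genes, which are not independent replicates.

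**Figure D1:**
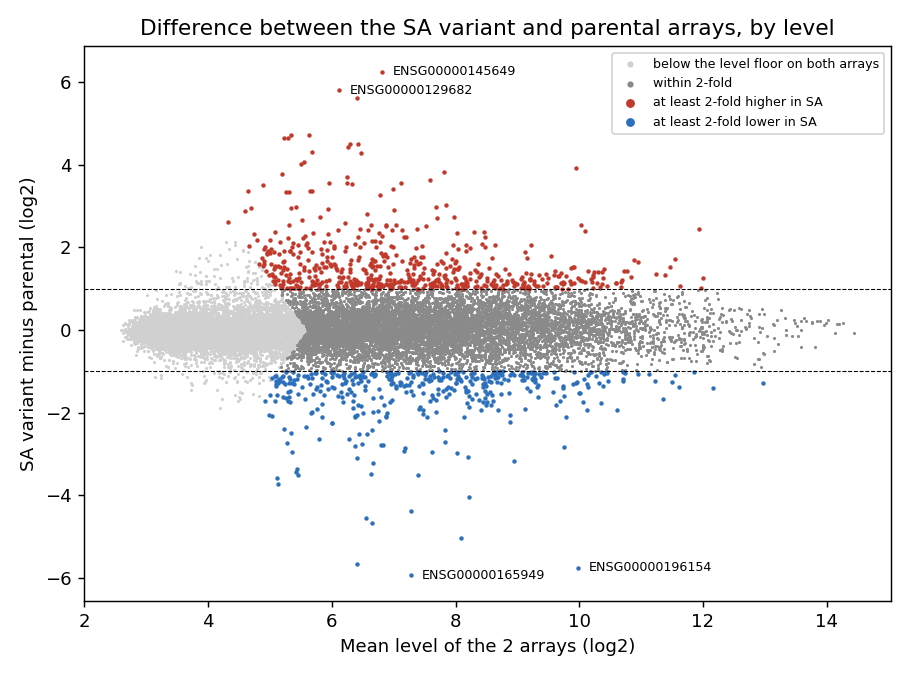
Difference between the arrays (SA variant minus parental, log2) against the mean level of both arrays (log2), 1 point per gene. Red points mark the 559 genes at least 2-fold higher in the SA variant, blue points the 406 at least 2-fold lower, light grey points the 8669 genes below the level floor on both arrays, and dashed lines a 2-fold difference. The 4 genes labelled by Ensembl ID have the largest differences of the deposited values in each direction, at 6.26 and 5.81 upward and at -5.94 and -5.75 downward; in all but ENSG00000196154 the lower level lay below the floor, so the size and rank rest on a dim value.

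In 3 of the 4 genes named here, the lower level lay below the floor. ENSG00000145649 had a level of 3.68 on the parental array and 9.93 on the SA array, a difference of 6.26 (76.6-fold). ENSG00000129682 was at 3.21 on the parental array and at 9.02 on the SA array, a difference of 5.81 (56.0-fold). In the other direction, ENSG00000165949 was at 10.2 on the parental array and at 4.31 on the SA array, a difference of -5.94 (61.5-fold lower). ENSG00000196154 was at 12.9 on the parental array and, still above the floor, at 7.11 on the SA array, a difference of -5.75 (53.8-fold lower). The levels of 3.68, 3.21 and 4.31 lay near or below the 25th percentile of all values, 4.12, where RMA values hold mostly background. Background alone would make these folds too small if the gene was silent there, while choosing the largest differences can make them too large.

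Larger differences were fewer in both directions. At least 4-fold higher in the SA variant were 107 genes, against 59 at least 4-fold lower. The 8-fold size was reached by 32 genes upward and 19 downward, and the 16-fold size by 14 and 8. Past 32-fold the numbers were 3 higher and 4 lower.

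**Figure D2:**
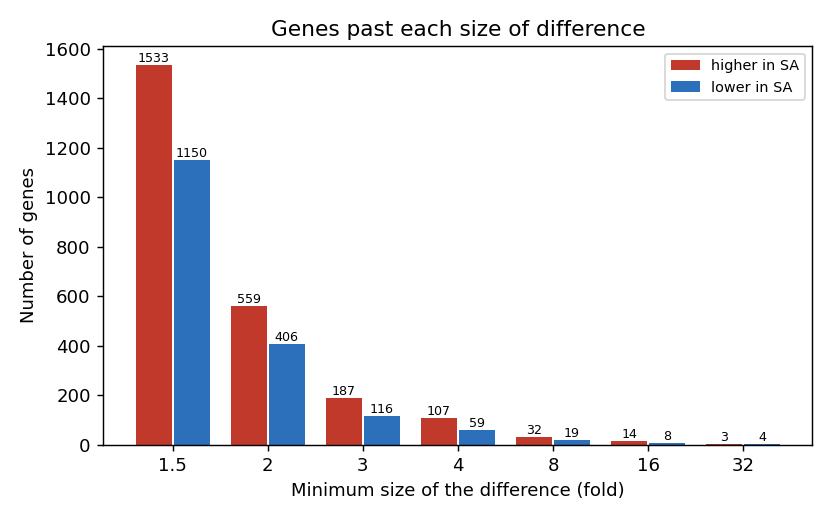
Number of genes (vertical axis) past each minimum size of difference in fold (horizontal axis), among the 9725 genes compared. Red bars count genes higher in the SA variant and blue bars genes lower, with the number above each bar. The red bar is the taller one at each size up to 16-fold, and past 32-fold there are 3 genes against 4.

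Most of the genes past the 2-fold size were above the floor in both lines, but a smaller share than among all genes compared. Of those 9725 genes, 8669 reached the floor on both arrays. A large difference by itself makes it more likely that a gene lies below the floor on 1 array. The smaller share therefore follows at least in part from the size rule. Of the 559 higher genes, 358 (64.0%) reached the floor on both arrays and 201 (36.0%) lay below it on the parental array. Of the 406 lower genes, 283 (69.7%) reached the floor on both arrays and 123 (30.3%) lay below it on the SA array. A level below the 25th percentile of all values in the parental line and at or above the 75th in the SA variant was seen for 8 genes, and the opposite for 1.

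Among the 2-fold genes, 57.9% were higher in the SA variant (exact 95% binomial interval 54.7% to 61.1%, which covers counting error only and takes genes as independent). The share moved to 52.3% when the 2 arrays' values were quantile normalized to each other, with 504 genes higher and 460 lower. The compared genes were also divided by mean level into 5 classes of 1945 genes. In the dimmest class 168 genes were higher and 96 lower, and in the brightest 84 were higher and 72 lower. In the class next to the brightest, with mean levels from 7.96 to 9.13, 87 were higher and 90 lower. A gene with a mean level well below the floor was compared only if its difference was large enough to reach the floor on 1 array. Part of the 2-fold calls in the dimmest class therefore follows from the floor rule. Their larger number does not show that 2-fold differences depend on level. The robust SD of the difference lay between 0.47 and 0.54 in all 5 classes. The SD of the difference was 0.33 among the 8669 genes below the floor on both arrays and 0.68 among the genes compared. A dim gene with a large difference tended to reach the floor on 1 array and was then among the genes compared. These 2 SDs therefore do not show that dim genes vary less.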

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

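No result could be repeated without a replicate, since each line had 1 array, and no paired analysis was possible because there was 1 array per group. The named genes were chosen as the largest differences, so the alternatives could not take them below 2-fold; with the floor required on both arrays, 3 of the 4 were not compared, all but ENSG00000196154. With a floor at the 25th percentile or none, or after centring, trend subtraction or quantile normalization, the counts of higher and lower genes stayed within 1.5 times the values reported. With the floor at the 75th percentile they were 308 higher and 256 lower, and with the floor required on both arrays 358 were higher. A size rule of 1.5-fold gave 1533 higher and 1150 lower, and a rule of 3-fold gave 187 and 116. The share of 2-fold genes that were higher was 54.6% with the floor at the 75th percentile, 52.98% after centring, 53.7% after trend subtraction, 52.3% after quantile normalization and 61.7% with the 3-fold rule. Pearson r was 0.954, 0.845 and 0.936 with the floor at the 25th percentile, at the 75th and on both arrays. The whole cell cycle list no longer stood apart with the floor at the 25th percentile (-0.027 relative to random lists), after trend subtraction (-0.032), after quantile normalization (-0.031) and by its mean (-0.022). The G2/M list no longer did with no floor (-0.089) and by its mean (-0.030). A size rule changes the counts by definition. Centring lowers every difference by the median of the genes compared, 0.045, which by itself lowers the share of higher genes. Trend subtraction likewise took that median to 0.005. A floor narrows the range of levels, which by itself can lower Pearson r. A floor set higher or required on both arrays can only take genes out of the counts. Quantile normalization pulls the share towards an even split whether the excess is technical or real. The cause of the other changes was not tested. Dim signal limits the folds of genes below the floor on 1 array.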

Other observations

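The cell cycle lists, the tests on them, the share of higher genes, its tests and the quantile normalization were all chosen after the data had been seen; for the S and G2/M lists, the measure and its bounds were set before their values were computed. Genes annotated to the cell cycle passed the 2-fold size less often than random lists of genes matched on level. Of the 1314 in the list, 1022 were compared, of which 37 were at least 2-fold higher and 27 at least 2-fold lower in the SA variant. That is 6.26%, against a median of 9.10% in 10000 matched random lists, of which the central 95% ran from 7.44% to 10.8%. None of the alternatives was run for this share. The median difference of the 1022 genes was 0.012, against 0.047 in matched random lists, at percentile 1.68 of these. This call was lost under 4 alternatives, at percentile 2.69 with the floor at the 25th percentile, 3.15 after trend subtraction, 3.24 after quantile normalization and 13.3 by the mean. Genes of the S phase list had a median difference of -0.076 (173 genes compared, 5 at least 2-fold higher and 6 lower), and those of the G2/M list -0.075 (105 genes, 3 higher and 2 lower). The G1 list had a median of 0.023 (172 genes, 10 higher and 2 lower), at percentile 27.0.

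A hypothesis from these lists is that the SA culture held a smaller share of cells in S phase when RNA was taken. The median of the S phase list lay at percentile 0.28 of the random lists, and it stood apart under the 9 alternatives run that could have moved it, at percentiles from 0.17 to 1.02. Centring moves all genes alike and could not. The alternatives reuse the same 2 arrays and largely the same genes, so they add no independent support. The S list's median minus that of the G1 list was -0.0996, in the direction the hypothesis predicts. This lay at percentile 6.24 of 10000 reassignments of the members of both lists, so a shift of this phase alone was not shown. For a smaller share of cells in G2 or M phase the evidence is mixed. The median of the G2/M list lay at percentile 1.72, but with no floor it lay at percentile 3.59, and the mean of the list lay at percentile 31.9. Relative to random lists the list was lower by both measures, -0.120 by its median and -0.030 by its mean, although the mean difference itself was 0.020. Its distance from the G1 list lay at percentile 14.9 of such reassignments, so, as for the S list, a shift of this phase alone was not shown. The phase lists are parts of the whole cell cycle list, 4 lists were tried, and the S list's median corresponds to a level in the SA variant of 0.948 times that in the parental line. Growth state on the day of harvest, a lasting property of the variant and a technical difference between the 2 arrays all stay open. They were not tested, as each line had 1 culture and 1 array, and the planned check of RNA quality could not be run.

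More genes were at least 2-fold higher than lower in the SA variant. Quantile normalization of the arrays to each other gave a share of higher genes of 52.3% (exact 95% binomial interval 49.1% to 55.5%), and 59.6% (51.6% to 67.3%) among genes past the 4-fold size, with 96 higher and 65 lower. Making the distributions equal pulls the share towards an even split whether the excess is technical or real, so these values do not decide whether a remaining difference between the arrays' distributions caused it. Asking for the floor on both arrays gave 55.9% (51.9% to 59.7%), which does not decide about noise in dim genes either, because a large change itself puts a gene below the floor on 1 array, and genes dim on both were already left out. A difference in distribution, noise in dim genes and a true excess of activated genes in the variant cannot be told apart with 1 array per line.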
